A study of Homo sapiens with 9 samples.

How the data were processed

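Gene expression was measured with 1-colour (Cy3) Agilent arrays, 1 array per RNA sample, in 3 groups of 3 samples of human breast adenocarcinoma cells. The groups were MCF7 with 1 nM oestradiol (MCF7_plus_E2), MCF7 after 3 days without oestrogen (MCF7_minus_E2), and LTED, the long-term oestrogen-deprived derivative of MCF7. The titles and cell type labels of the MCF7_minus_E2 samples name the line as MCFT, and it was taken as MCF7, which their descriptions name. The design text names 3 independent RNA extractions and the labels do not say whether these came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The array images were read with Feature Extraction version 10.7.3.1 per the file headers. Per the file headers, the processed signal of each spot is an intensity on a linear scale, after background subtraction within the array and with no normalization between arrays. The median signal and the median local background of each spot are raw intensities, per the file headers. The values that the authors deposited in the series matrix are on the log2 scale, and a check of the columns found quantile normalized values, since the sorted columns differ by at most 0.000852.

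Each array held 62976 spots, of which 4259 were controls. The files carry no gene names, so each of the 42405 non-control probes took its symbol from its transcript identifier through a reference table of human transcripts, which gave 27235 probes a symbol and left 15170 without one. Because the array was designed on an older genome build than the table, only symbols and the order of genes were used, and no coordinates are given. Spots that the scanner software marked as outliers were left out, spots of the same probe were averaged, and each log2 signal had the array's 75th percentile over non-control spots subtracted. A probe was kept if it was well above background on all arrays of at least 1 group, which kept 22902 probes. The brightest kept probe stood for each gene, and 13414 genes with values on all arrays were tested. The 75th percentile of the signal ran from 606 to 1165 between arrays, between 51.0% and 62.0% of probes were well above background, and 0 spots were saturated. MCF7_plus_E2 replicate 1 had the highest of both values. The quality summary in the file headers marked that array for evaluation and read in range for all others. The number of arrays limits the precision.

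All 9 arrays entered one fit in limma 3.58.1 under R 4.3.3, with moderated two-sided tests of the 3 pairwise comparisons, an F-test over the 3 groups, Benjamini-Hochberg adjustment over all genes of a comparison, and a call at an adjusted p under 0.05. Where a gene was above background on no array of one group, values under the lowest signal called above background on that array were set to it, and the resulting fold is given as a bound ("at least N-fold"). These bounds hold on the scale of the processed signal. The normexp alternative adds 50 to each signal, which draws folds of dim genes towards 1, and it gave the smallest fold of all alternatives for each named gene with a bound, so its value is given beside the bound. The same floor was applied to named genes above background on some arrays of a group, and the value is given where it moves a call's size by 10% or more. Gene lists were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over 87 tests (29 lists with at least 5 measured members, 3 comparisons), and again with an estimated correlation. Some genes are in more than 1 list, so the list tests are not independent of each other. Calls shared by the comparisons that use the same MCF7_minus_E2 arrays were set beside independent calls and beside 100 simulated data sets without effects. Tested on simulated data, the fit recovered 55%, 51% and 60% of genes changed by a log2 fold change of 1 and 81%, 88% and 88% of those changed by 2, in the order MCF7_plus_E2 against MCF7_minus_E2, LTED against MCF7_minus_E2 and LTED against MCF7_plus_E2. Of the simulated calls, 7.48%, 4.79% and 5.73% were false in the same order. Each comparison had 1 simulated data set, in which 200 of 13414 genes changed. Genes varied independently there, and each gene had the same spread in all groups. On the real arrays 3.20%, 23.6% and 36.5% of genes were called and the spread differed between groups, so these rates need not hold for them. A list of 25 genes shifted by 0.5 was found in 20 of 20 draws in each comparison, and 2, 1 and 1 of 20 unshifted lists were called. These lists were judged by camera at an unadjusted p under 0.05, and their genes were drawn at random and varied independently. The draws therefore do not cover lists of correlated genes, and the estimated correlation of the G1/S and DNA replication list was 0.885.

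The groups, the comparisons and their tests, 30 gene lists and the rule for named genes were fixed before the data were examined. So were the alternatives, except for the block for pairs of slide columns, the block on the 6 MCF7 arrays, the fits on replicates 1 and 2 only, and the list tests without each array other than LTED replicate 3, which were added later. Genes are named from 15 fixed genes (EGFR was not kept by the filter), the 8 highest and 8 lowest called genes per comparison that were above background on all arrays and whose groups did not overlap, the 4 largest bounds in each direction, and 2 to 4 members of each list with the largest change. A few were added after their values were seen, and the text says which. Alternatives covered the normalization (quantile, normexp with an offset of 50, and the authors' values), the filter on dim probes, the choice of probe, the arrays in the fit, the variance prior, blocks for replicate number, for slide and for pairs of slide columns (1 and 2 against 3 and 4, from the file names), a size threshold of 1 on the log2 fold change, and each array left out in turn. The normexp alternative used median signals because mean signals are not in the columns used here. Deviations from group means correlated across genes by 0.44, 0.26 and 0.48 between same-numbered arrays of the MCF7 groups, so the numbers were taken to pair these arrays and the values with replicate number as a block are given where they differ. Between these groups, replicate 1 of one and replicate 2 of the other correlated by 0.28 and 0.29, and replicate 3 of one with replicates 1 and 2 of the other by −0.45 to −0.33, so replicate 3 against replicates 1 and 2, in place of 3 pairs, stays open. Between LTED and MCF7_minus_E2 these correlations were 0.11, 0.04 and 0.13, and between LTED and MCF7_plus_E2 0.05, −0.01 and −0.07. Replicates 1 and 3 of both MCF7 groups also shared columns 4 and 1 of the slide, so number and place on the slide cannot be told apart for them. LTED replicate 3 was alone on another slide and scanned on another day than the other 8 arrays, so slide and scan day are the same split and were run as 1 alternative. Probes without a symbol were left out of the gene tests. Figures were drawn with matplotlib 3.10.9.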

Results

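Transcript levels of 13414 genes were compared between 9 arrays of MCF7, an oestrogen receptor positive breast adenocarcinoma line, and its long-term oestrogen-deprived derivative LTED. All cells were kept in medium with stripped serum, and 3 samples each stood for MCF7 with 1 nM oestradiol, MCF7 after 3 days without oestrogen, and LTED. The stated theme of the series is the availability of amino acids and metabolic reprogramming in endocrine resistance. Over the 3 groups, 4646 genes differed by the limma F-test, with 7260 without MCF7_plus_E2 replicate 3 and 3093 and 3026 without LTED replicates 1 and 2. All values below are log2 fold changes with their standard error (SE), or folds, over n = 3 arrays per group, and adjusted p-values come from limma.

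The arrays of LTED lay apart from those of MCF7 along the first principal component, which held 62.5% of the variance. MCF7_plus_E2 replicate 3 lay at −46.9 on the first component, near replicates 1 and 2 of its group at −49.9 and −49.25. The MCF7_minus_E2 arrays lay between −31.5 and −18.95 there. On the second component (18.4% of the variance) MCF7_plus_E2 replicate 3 lay at −29.9, where replicates 1 and 2 of its group lay at 43.1 and 46.6. Across genes, which are not independent replicates, its correlation was 0.990 with MCF7_minus_E2 replicate 3 and 0.967 with each other array of its own group. Its mean for the oestrogen-induced genes was 0.62 relative to each gene's mean over the 9 arrays, against 0.81 and 0.83 in replicates 1 and 2 and −0.13 to 0.08 in MCF7_minus_E2. For genes of G1/S and DNA replication its mean was 0.77, against −0.75 in both other arrays of its group. For the ATF4 amino acid response list its mean was −0.01, against 1.47 and 1.58.

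**Figure D1:**
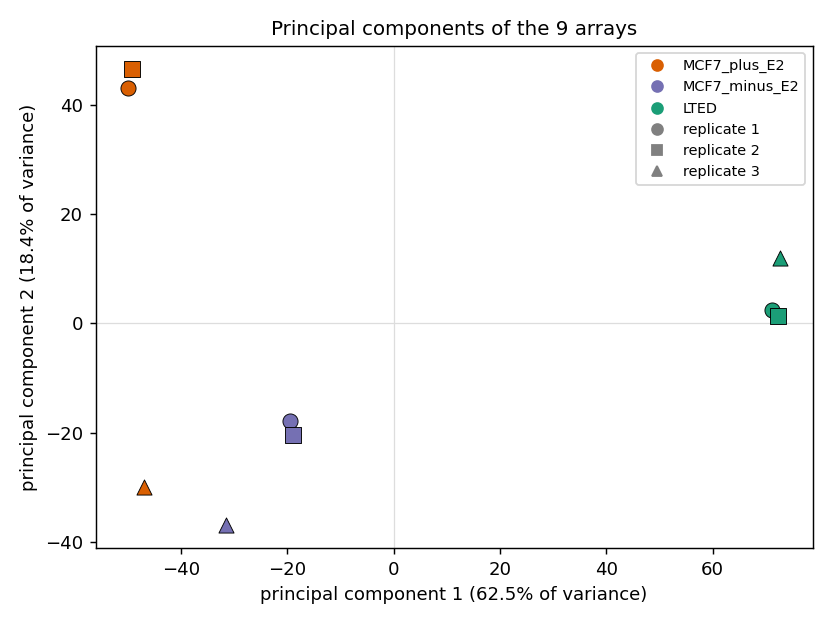
First and second principal components of the 9 arrays, with colour for the group and symbol for the replicate number. On the first component the LTED arrays sit between 71.1 and 72.7, the MCF7_plus_E2 arrays between −49.9 and −46.9 and the MCF7_minus_E2 arrays between −31.5 and −18.95. MCF7_plus_E2 replicate 3 sits at −29.9 on the second component.

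The comparison of MCF7_plus_E2 with MCF7_minus_E2 addresses the response to oestradiol. With oestradiol, CCN5, a known oestrogen-induced gene, was 4.03 times as high (2.01, SE 0.22, adjusted p = 0.00772), and INSYN1 was 4.44 times as high (2.15, SE 0.14, adjusted p = 0.000565). ACKR3, an atypical chemokine receptor, was lower by a log2 fold change of −2.88 (SE 0.19), and PPP1R3C, a regulator of glycogen synthesis, by −3.05 (SE 0.30). NPNT, an extracellular matrix protein, stood at −2.34 (SE 0.21), the sialyltransferase ST6GALNAC2 at −2.29 (SE 0.17) and PSCA, a cell surface antigen, at −3.26 (SE 0.37). ESR1, which encodes the oestrogen receptor itself, fell by 1.19 (SE 0.21, adjusted p = 0.03). The tubulin genes TUBA3D and TUBA3C rose by 3.98 and 3.61 and the pseudogene TUBA3FP was at least 21.2-fold higher (4.95-fold with normexp), but their sequences are nearly identical, so which of them changed is uncertain. Among fixed genes that were not called, GREB1 had 0.68, MYC 0.65, SLC7A5 1.42 (adjusted p = 0.0532), SLC7A11 3.31, ASNS 2.09, SLC1A5 0.52, ERBB2 −0.78, SLC1A2 −0.32, GLS −0.24, SLC6A14 −0.18, CCND1 −0.06, PGR 0.09 and TFF1 0.09. In all, 429 genes were called, 157 higher and 272 lower, and 64 and 178 of these changed at least 2-fold. The LTED arrays entered the estimate of the spread, with SDs per array of 0.118 to 0.243. Between MCF7_plus_E2 replicate 3 and replicates 1 and 2 these were 0.416 and 0.385. The adjusted p-values of this comparison may therefore understate the spread between its own arrays. On only the 6 arrays compared, without a block, 17 genes were called. The groups did not overlap for 24.6% of genes, where chance gives 10% on average. Genes vary together between arrays, so a single wrong grouping can depart from that average, here and in the comparisons below. A wrong split of these 6 arrays had 3052 genes at an unadjusted limma p under 0.05, against 3037 for the real one. With replicate number as a block, 94 genes were higher and 194 lower, and with pairs of slide columns as a block 49 and 136. Blocked by replicate number on the 6 MCF7 arrays alone, 8 were higher and 5 lower (3627 at an unadjusted p under 0.05). Of the named genes called in this comparison, TUBA3D, TUBA3C, TUBA3FP, INSYN1, ACKR3, ST6GALNAC2 and EGR3 kept their calls there and 41 lost them (adjusted p up to 0.129), with CCN5 at 0.0722, PPP1R3C at 0.0712, NPNT at 0.0722, PSCA at 0.07 and ESR1 at 0.103. Without MCF7_plus_E2 replicate 3 the total was 3702, without MCF7_minus_E2 replicate 3 it was 741, without LTED replicates 1 or 2 it was 81 or 99, and without MCF7_plus_E2 replicates 1 or 2 it was 29 or 32. Without MCF7_minus_E2 replicates 1 or 2 it was 18 or 22. Other genes at the extremes were LAMP3 (2.63, SE 0.53), ZNF385B (2.58, SE 0.44), OSBPL6 (2.23, SE 0.45), BMP5 (2.22, SE 0.41), PMP22 (−2.52, SE 0.46) and TM4SF1 (−2.49, SE 0.51). Their calls were lost with the block (adjusted p up to 0.0655), without replicate 1 of any group, MCF7_plus_E2 or MCF7_minus_E2 replicate 2 and, but for ZNF385B, LTED replicate 2 (up to 0.179), and for TM4SF1 also without LTED replicate 3. The call on ESR1 was lost without replicate 1 or 2 of any group, with adjusted p-values up to 0.15, and those on CCN5 and PSCA were lost without MCF7_minus_E2 replicate 1 (0.0502 and 0.0507).

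Genes that oestrogen is known to induce were higher with oestradiol as a list. Of 29 measured members, 7 rose, 0 fell and 22 were not called, with EGR3 at 4.41 (SE 0.66, and 3.04 with normexp) and above background on 2 of 3 MCF7_minus_E2 arrays, and MYBL1 at 1.58 (SE 0.25) and PDZK1 at 1.52 (SE 0.33) beside CCN5. Adjusted over the list alone, 15 rose. The list's median was 0.65, with camera adjusted p = 8.12e-09, and adjusted p = 0.16 with an estimated correlation. Of 12 genes that oestrogen is known to repress, 3 fell and 0 rose: the proapoptotic gene BMF at −1.54 (SE 0.24), YPEL3 at −1.56 (SE 0.22), and the interleukin receptor gene IL1R1, at least 4.32-fold lower (1.43-fold and not called with normexp, adjusted p = 0.111). When adjusted over the list alone, 6 fell, and the median was −0.82 (camera adjusted p = 5.3e-05, and adjusted p = 0.924 with an estimated correlation). Of 18 genes for the oestrogen receptor and its co-regulators, ESR1 and PBX1 (−0.97, SE 0.19) fell and 0 rose (5 called when adjusted over the list alone, 1 higher and 4 lower), and camera gave an adjusted p of 0.119. With the block 1 of these rose and 1 fell, PBX1 and PDZK1 lost their calls (adjusted p 0.0663 and 0.0667), and without MCF7_plus_E2 replicate 3, 3 rose and 5 fell. Without MCF7_minus_E2 replicate 3, 4 of them fell with camera at 0.0188, and without replicate 1 or 2 of any group 0 fell. With 1 array left out, the number of induced genes that rose was 13 (and 1 fell) without MCF7_plus_E2 replicate 3, 3 without LTED replicate 1 or 2, 1 without MCF7_plus_E2 replicate 1 or 2 or MCF7_minus_E2 replicate 2, and 0 without MCF7_minus_E2 replicate 1. The number of repressed genes that fell was 0 without MCF7_plus_E2 replicate 1 or 2 or MCF7_minus_E2 replicate 1, and 1 without MCF7_minus_E2 replicate 2, and camera's adjusted p for them was 0.0661 without MCF7_plus_E2 replicate 3. PBX1, MYBL1 and PDZK1 lost their calls without replicate 1 or 2 of any group (adjusted p up to 0.179, 0.123 and 0.194), PDZK1 also without MCF7_minus_E2 replicate 3, and EGR3, YPEL3 and BMF lost theirs without replicate 1 or 2 of either MCF7 group (0.0912, 0.0969 and 0.111). IL1R1 lost its call without MCF7_plus_E2 replicate 1 or 2 or MCF7_minus_E2 replicate 1 (0.078).

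Genes of the ATF4 response to amino acid shortage stood higher in the presence of oestradiol as a list, with a median of 1.42. Of 26 measured members 1 rose, 0 fell and 25 were not called: CHAC1, which encodes a glutathione-degrading enzyme, rose by 4.06 (SE 0.86, adjusted p = 0.0441), while DDIT3 had 2.87 (SE 0.84) and VEGFA 2.29 (SE 0.69). Adjusted over the list alone, 19 rose, with camera adjusted p = 4.09e-09 and adjusted p = 0.924 with an estimated correlation. In the unfolded protein response list 4 of 17 rose (7 when adjusted over the list alone) and 0 fell, with MANF at 0.92 (SE 0.20) and DNAJB11 at 0.75 (SE 0.12), and camera gave adjusted p = 1.02e-06, and adjusted p = 0.599 with an estimated correlation. In the ribosome biogenesis list, RRP12 (0.82, SE 0.18) and WDR43 (0.65, SE 0.14) rose out of 25 (9 when adjusted over the list alone) and 0 fell, and camera gave adjusted p = 3.44e-05, and adjusted p = 0.813 with an estimated correlation. Of 25 measured amino acid transporters 0 rose and 0 fell by limma (8 at an unadjusted p under 0.05, and 2 rose when adjusted over the list alone), with SLC3A2 at 1.68 (SE 0.42) and SLC43A1 at 1.88 (SE 0.74), and camera gave adjusted p = 0.221. Of 31 enzymes of aspartate, glutamate and related amino acids, GOT1 rose by 1.06 (SE 0.20), and ALDH4A1 and PRODH, which act in proline breakdown, fell by 1.28 (SE 0.22) and 1.14 (SE 0.16). When adjusted over the list alone, 4 rose and 4 fell, and camera gave adjusted p = 0.803. The G1/S and DNA replication list had a median of −0.56 with 0 of 30 called by limma in either direction (1 at an unadjusted p under 0.05, 0 when adjusted over the list alone). CCNE2 had −1.69 (SE 0.75) there. Camera gave adjusted p = 0.00108, and adjusted p = 0.995 with an estimated correlation. MCF7_plus_E2 replicate 3 stood apart for the ATF4 and replication lists. Its means were nearer to replicates 1 and 2 for the unfolded protein response (0.39, against 0.45 and 0.66) and ribosome biogenesis (0.25, against 0.08 and 0.19). With this array left out, 21 ATF4 response, 9 unfolded protein response, 8 ribosome biogenesis and 8 transporter genes rose, 2 transporters fell, 8 enzymes rose and 6 fell, and 25 replication genes fell. With the block 0 ATF4 response genes and 1 ribosome biogenesis gene rose, 0 enzymes rose and 1 fell, and CHAC1, GOT1, ALDH4A1, RRP12 and WDR43 lost their calls (adjusted p 0.0755, 0.0593, 0.0539, 0.0723 and 0.0554). Without replicate 1 or 2 of any group, 0 genes of the ATF4, unfolded protein and ribosome biogenesis lists rose, and CHAC1, MANF, DNAJB11, RRP12, WDR43, GOT1 and ALDH4A1 lost their calls (adjusted p up to 0.191, 0.2, 0.135, 0.194, 0.193, 0.158 and 0.144). PRODH lost its call without replicate 1 or 2 of either MCF7 group (0.0969). CHAC1 and WDR43 also lost theirs without MCF7_minus_E2 replicate 3, and MANF and RRP12 without LTED replicate 3, where 4 ATF4 response genes, 3 transporters and 1 ribosome biogenesis gene rose. Without LTED replicate 1 or 2, 0 enzymes rose and 1 fell, and without replicate 1 or 2 of either MCF7 group 0 enzymes were called. The camera call on replication genes was lost without MCF7_plus_E2 replicate 1 or 2 or MCF7_minus_E2 replicate 3 (adjusted p 0.0967, 0.0703 and 0.132).

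Camera also called 2 more lists between the MCF7 groups. Oxidative phosphorylation genes had a median of 0.12, with CYCS, cytochrome c, at 0.64 (SE 0.30) and 0 of 39 called by limma (7 at an unadjusted p under 0.05, 0 when adjusted over the list alone). By camera the adjusted p was 0.0495, and adjusted p = 0.924 with an estimated correlation. Receptor tyrosine kinases and adaptors had a median of −0.56, and 1 of 19, ERBB4, fell, by 1.71 (SE 0.29), while FGFR3 had −2.02 (SE 0.67). Adjusted over the list alone 1 rose and 6 fell, with camera adjusted p = 0.0245, and adjusted p = 0.924 with an estimated correlation. The camera call for oxidative phosphorylation was lost with the replicate block (0.0508), and without MCF7_plus_E2 replicate 3 (0.617), MCF7_minus_E2 replicates 1, 2 and 3 (0.0706, 0.0786 and 0.0575) or LTED replicate 1 (0.0507), and that for receptor tyrosine kinases without MCF7_plus_E2 replicate 3 (0.241) or MCF7_minus_E2 replicate 1 (0.0536). ERBB4 lost its call without replicate 1 or 2 of any group (adjusted p up to 0.135), leaving 0 kinases called. Without LTED replicate 3 or MCF7_minus_E2 replicate 3, 2 kinases fell, and without MCF7_plus_E2 replicate 3, 3 rose and 6 fell, and 3 oxidative phosphorylation genes rose and 1 fell.

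**Figure D2:**
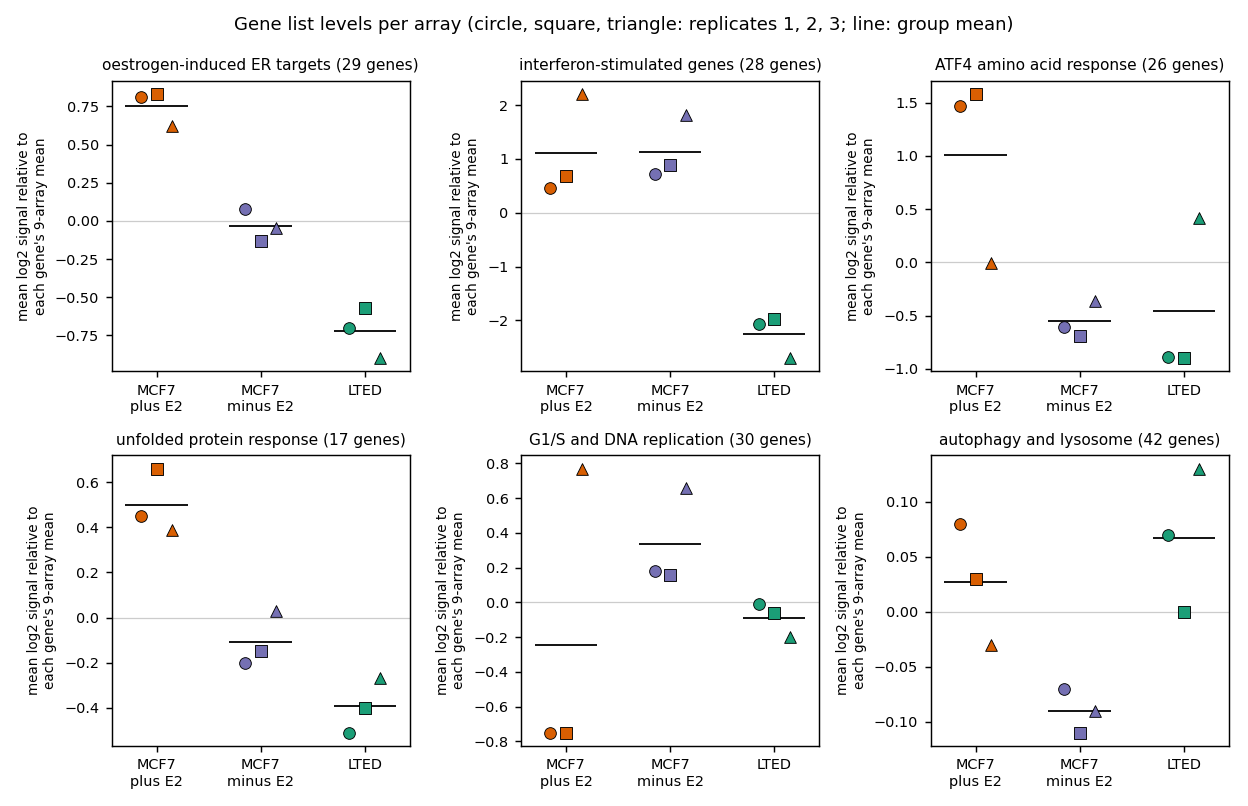
Mean log2 signal of 6 gene lists per array, relative to each gene's mean over the 9 arrays; points are arrays (circle, square and triangle for replicates 1, 2 and 3) and lines are group means. Interferon-stimulated genes lie between −2.70 and −1.98 in LTED and between 0.46 and 2.20 in MCF7, and MCF7_plus_E2 replicate 3 lies apart from its group for the ATF4 and the replication lists, as LTED replicate 3 does for the ATF4 list (0.42 against −0.89 and −0.90).

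The comparison of LTED with MCF7_minus_E2 sets long-term against 3-day deprivation in matched medium. The design holds a single LTED derivation, so the length of deprivation cannot be told apart from other differences of the derived line. LTED cells had much more COL12A1, a collagen (7.41, SE 0.15, adjusted p = 6.58e-08), SLC24A3, a sodium, potassium and calcium exchanger (6.05, SE 0.46), and PCP4, a calmodulin-binding protein (5.14, SE 0.20). The lectin gene CLEC3A was at least 305-fold, BRINP3 at least 210-fold and the chromatin organiser SATB1 at least 150-fold higher. With normexp these were 65.8-fold, 32.4-fold and 24.9-fold. SLC6A14, a transporter of neutral and basic amino acids, was lower by −7.98 (SE 0.37, adjusted p = 4.22e-06), but only 1 of the 3 LTED arrays measured it above background, and the difference was −7.16 with lower signals set to the array's floor and −4.91 with normexp. MUCL1, a small mucin, stood at −6.67 (SE 0.55), the growth factor gene AREG at −4.91 (SE 0.41), the sulfate transporter gene SLC26A2 at −4.69 (SE 0.36). The kallikrein gene KLK11 was at least 189-fold lower (32.8-fold with normexp). ESR1 rose by 1.56 (SE 0.21, adjusted p = 0.0011), whereas the oestrogen receptor targets PGR, TFF1 and GREB1 fell by 1.25 (SE 0.26), 0.94 (SE 0.15) and 2.09 (SE 0.28). Genes of the MAGEA and CSAG families of cancer-testis antigens rose, with CSAG1 at 5.64 and MAGEA6 at 4.94, and UGT1A6 fell by 4.95, but near-identical family members leave open which of them changed. Of 13414 genes, 3168 were called, 1720 higher and 1448 lower, and 779 and 688 of these changed at least 2-fold. The groups did not overlap for 51.5% of genes, where chance gives 10% on average. Without MCF7_plus_E2 replicate 3 the total was 4754, and without LTED replicate 1 or 2 it was 2101 or 2095, with 1093 or 1080 higher. Without MCF7_minus_E2 replicate 1, 951 were lower.

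Interferon-stimulated genes, which respond to antiviral signalling, were much lower in LTED. Of 28 measured members, 23 fell and 0 rose (25 fell when adjusted over the list alone), with a median of −2.94. IFI44L was at least 254-fold and OAS1 at least 32.1-fold lower (48.7-fold and 5.99-fold with normexp). IFI6 stood at −6.03 (SE 0.67), IFIT1 at −5.02 (SE 0.64) and IFI44, which only 2 of the 3 LTED arrays measured above background, at −7.05 (SE 0.49; −5.45 with normexp). The camera test gave adjusted p = 9.82e-16, and adjusted p = 0.814 with an estimated correlation. Against MCF7_plus_E2, 23 also fell and 0 rose (24 fell when adjusted over the list alone), with a median of −3.18, or −3.14 with bounds in place of fitted values. There camera gave adjusted p = 4.04e-12, and adjusted p = 0.924 with an estimated correlation. Replicate 3 of both MCF7 groups had the highest means for this list, 2.20 and 1.81, against 0.46 to 0.88 in their other arrays. Between the MCF7 groups 1 of 28, ISG20, rose, by 1.79 (SE 0.26), and 2 rose when adjusted over the list alone. With MCF7_plus_E2 replicate 3 left out, 2 rose and 8 fell in that comparison, without MCF7_minus_E2 replicate 3, 3 rose, and without replicate 1 or 2 of either MCF7 group 0 rose and ISG20 lost its call (adjusted p up to 0.0969).

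Oestrogen-induced genes were lower in LTED than in MCF7_minus_E2, although neither group received oestradiol. Of 29 measured, 14 fell and 0 rose (14 fell and 1 rose when adjusted over the list alone), including AREG, GREB1 and the protease gene PRSS23 at −2.35 (SE 0.45). The median was −0.54, with camera adjusted p = 0.00284, and adjusted p = 0.688 with an estimated correlation. Of 12 oestrogen-repressed genes, 3 rose and 0 fell (3 rose when adjusted over the list alone), among them IL1R1 at 1.96 (SE 0.32, and 0.96 with normexp) with 2 of 3 MCF7_minus_E2 arrays above background, and BCAS1 at 1.64 (SE 0.29). Camera gave adjusted p = 0.339 for them. Of the receptor and co-regulator list of 18, ESR1 was among 2 that rose and GREB1 and the transcription factor gene TFAP2C (−2.05, SE 0.24) among 3 that fell, with the same counts adjusted over the list alone and camera adjusted p = 0.869. Without any 1 array of LTED replicates 1 and 2 or of MCF7_minus_E2 only 1 receptor or co-regulator gene rose, and without MCF7_plus_E2 replicate 3 or MCF7_minus_E2 replicate 3, 2 and 1 oestrogen-induced genes rose. Without MCF7_minus_E2 replicate 3, 1 repressed gene fell, and with the replicate block 3 oestrogen-induced genes rose.

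Genes of G2/M and mitosis were lower in LTED than in MCF7_minus_E2. Of 28 measured, 7 fell and 0 rose (7 fell when adjusted over the list alone), with the mitotic kinase gene AURKB at −1.20 (SE 0.19), CENPA, a centromeric histone, at −1.28 (SE 0.25) and NUSAP1 at −1.02 (SE 0.23). The median was −0.59, with camera adjusted p = 2.98e-05, and adjusted p = 0.924 with an estimated correlation. MCF7_minus_E2 replicate 3 stood above the other arrays of its group for these genes, with a mean of 0.57 against 0.05 and 0.15. The LTED arrays lay between −0.41 and −0.27. For G1/S and DNA replication 1 of 30, GINS3, fell, by 1.16 (SE 0.27), and 0 were called when adjusted over the list alone. By camera the adjusted p was 0.0495 for that list, and adjusted p = 0.995 with an estimated correlation. Without MCF7_plus_E2 replicate 3, 17 mitotic and 11 replication genes fell. Camera's call for replication genes was lost without LTED replicate 1, 2 or 3 (0.0506, 0.0609 and 0.109) or MCF7_minus_E2 replicate 3 (0.272), and GINS3 lost its call without MCF7_minus_E2 replicate 3 (0.0508), leaving 0.

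Amino acid transporters moved in both directions in LTED against MCF7_minus_E2. Of 25 measured, 7 fell and 2 rose (7 and 2 when adjusted over the list alone). Besides SLC6A14, the glutamate and aspartate transporter gene SLC1A3 was at least 4.6-fold lower (1.66-fold and not called with normexp, adjusted p = 0.0567). SLC1A1 stood at −2.93 (SE 0.42; −1.07 with normexp), with 1 of 3 LTED arrays above background. SLC1A2, another glutamate transporter, rose by 1.85 (SE 0.39; 0.98 with normexp) and was above background on 2 of 3 MCF7_minus_E2 arrays. SLC7A5, a transporter of large neutral amino acids, fell by 1.20 (SE 0.33), and SLC7A11 had −1.18 and SLC1A5 0.15 without a call. The camera test gave adjusted p = 0.118 for the list. Of 31 amino acid enzymes, 6 rose and 4 fell (6 and 4 when adjusted over the list alone). BCAT1, which starts the breakdown of branched-chain amino acids, was at least 5.71-fold higher (1.92-fold with normexp). OAT, ornithine aminotransferase, rose by 1.73 (SE 0.24), and the glutaminase gene GLS fell by 0.65 (SE 0.14), while ASNS had 0.32. Camera gave adjusted p = 0.579. SLC7A5 was also the only gene of 26 in the ATF4 response list that fell, and 0 rose (0 when adjusted over the list alone). The list's median was 0.24 and its mean 0.10, and camera, whose direction was down, gave adjusted p = 0.939. The number of transporters that fell was 3 without LTED replicate 1 and 4 without LTED replicate 2 or MCF7_minus_E2 replicate 1 or 2, and the number that rose was 1 without LTED replicate 2 or 3 or any array of MCF7_minus_E2. Of the enzymes, 1 fell without LTED replicate 2 or any array of MCF7_minus_E2, and 2 fell without LTED replicate 1 or 3. With the replicate block SLC7A5 lost its call (adjusted p 0.0531), as it did without LTED replicate 1 or 2 or any array of MCF7_minus_E2 (adjusted p up to 0.0993), where 0 ATF4 response genes fell, 3 of these fell without LTED replicate 3, 2 without MCF7_plus_E2 replicate 1, and 2 fell and 1 rose without MCF7_plus_E2 replicate 3. The camera value for transporters was 0.0159 without LTED replicate 3.

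Other lists fixed for LTED against MCF7_minus_E2 also moved in both directions. Of 42 autophagy and lysosome genes, 12 rose and 5 fell (12 and 5 when adjusted over the list alone), with the proton pump gene ATP6V1H at 1.58 (SE 0.17), the autophagy initiation gene RB1CC1 at 1.54 (SE 0.22) and the protease gene CTSD at −1.86 (SE 0.29). By camera the adjusted p was 0.418. Of 19 receptor tyrosine kinases and adaptors, 3 rose and 7 fell (3 and 8 when adjusted over the list alone), with a median of 0.04 and a mean of −0.07, ERBB4 at 3.14 (SE 0.29), FGFR3 at 3.22 (SE 0.67) and MET at −1.69 (SE 0.18). ERBB2 had 0.77 and MYC 1.00 without a call. Of 15 ERK pathway targets, 3 rose and 6 fell (4 and 6 when adjusted over the list alone), with EPHA4 at −3.39 (SE 0.37) and PHLDA1 at 1.68 (SE 0.22). The camera test gave adjusted p = 0.535 and 0.746 for these lists. In the list of cholesterol biosynthesis genes 2 of 23 rose and 3 fell (2 and 3 when adjusted over the list alone), CYP51A1 at −0.95 (SE 0.19) among them. Their median was −0.52, with camera adjusted p = 0.0488, and adjusted p = 0.995 with an estimated correlation. That camera call was lost without LTED replicate 3 (0.152) or MCF7_minus_E2 replicate 3 (0.243). Of the cholesterol genes, 8 fell without MCF7_plus_E2 replicate 3, 0 rose without LTED replicate 2 or MCF7_minus_E2 replicate 1 or 3, 1 rose without LTED replicate 1 or 3, and 1 fell without LTED replicate 2 or 3 or MCF7_minus_E2 replicate 3. CCND1, a cyclin gene, fell by 0.54 (SE 0.15) and lost its call without LTED replicate 1, 2 or 3 or MCF7_minus_E2 replicate 1 or 2 (adjusted p up to 0.0975). Of the autophagy genes, 7 rose and 3 fell without LTED replicate 1, 6 and 3 without LTED replicate 2, 7 rose without MCF7_minus_E2 replicate 3, and 3 fell without MCF7_minus_E2 replicate 1 or 2. Of the receptor tyrosine kinases, 4 fell without MCF7_minus_E2 replicate 1.

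**Figure D3:**
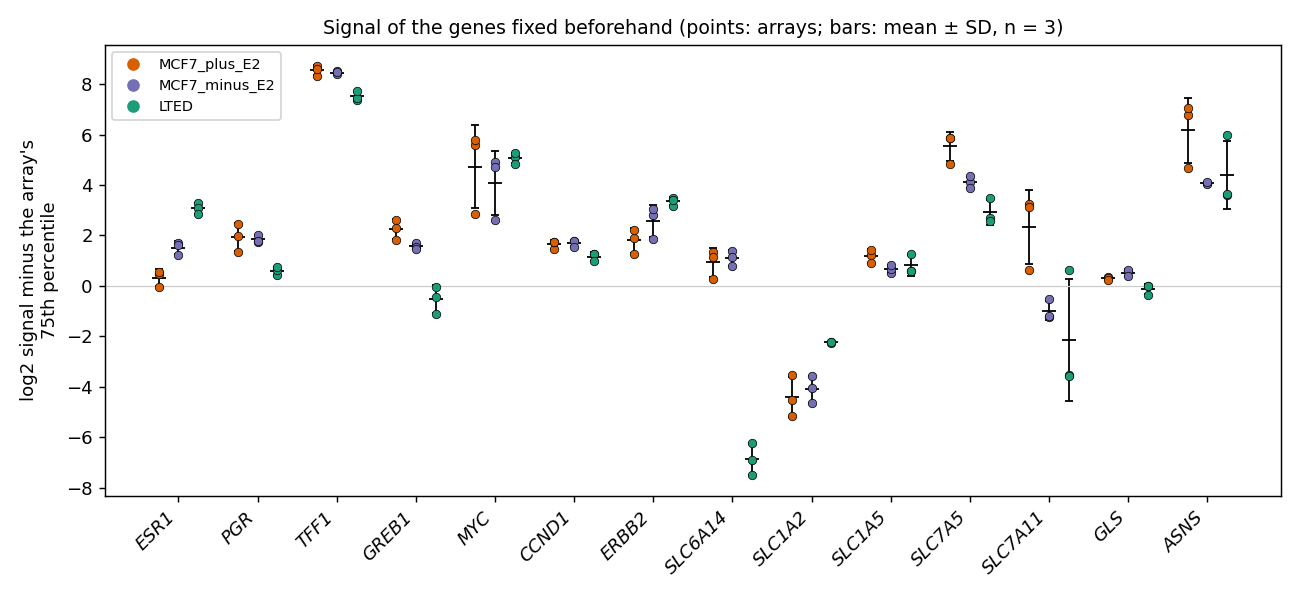
Log2 signal minus the array's 75th percentile for 14 genes fixed beforehand, with points for arrays and bars for the mean ± SD (n = 3) per group. SLC6A14 has means of 0.93, 1.11 and −6.87 in MCF7_plus_E2, MCF7_minus_E2 and LTED, where 1 of 3 arrays measured it above background.

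The comparison of LTED with MCF7_plus_E2 combines the derivation of LTED with the absence of oestradiol. ACKR3, which was lower with oestradiol, was 66.9 times as high in LTED (6.06, SE 0.19, adjusted p = 7.94e-07), and the adhesion molecule gene NCAM2 stood at 5.28 (SE 0.18), FGFR3 at 5.24 (SE 0.67), JPH1 at 5.21 (SE 0.34) and ERBB4 at 4.85 (SE 0.29). AREG stood at −6.43 (SE 0.41), PDLIM3 at −6.15 (SE 0.32) and EGR3 at −5.06 (SE 0.66). The transcription factor gene SOX3 was 32.1-fold lower, and PPM1K, a phosphatase of branched-chain amino acid breakdown, stood at −4.94 (SE 0.20). KLK11 was at least 458-fold and the cytokine gene IL24 at least 138-fold lower (76.1-fold and 22.1-fold with normexp). ESR1 rose by 2.75 (SE 0.21, adjusted p = 3.35e-05), ERBB2 rose by 1.55 (SE 0.33) and SLC1A2 by 2.17 (SE 0.39, and 1.09 with normexp), which 2 of 3 MCF7_plus_E2 arrays measured above background. SLC6A14, above background on 1 of 3 LTED arrays, fell by 7.80 (SE 0.37), or fell by 6.99 with lower signals set to the array's floor and by 4.70 with normexp. SLC7A5 fell by 2.62 (SE 0.33), GREB1 by 2.77 (SE 0.28), PGR by 1.34 (SE 0.26) and TFF1 by 1.03 (SE 0.15). SLC7A11 fell by 4.49 (SE 1.11, adjusted p = 0.0133), CCND1 by 0.48 (SE 0.15) and GLS by 0.42 (SE 0.14), while MYC had 0.35, ASNS −1.77 and SLC1A5 −0.37 without a call. In all 4897 genes were called, 2621 higher and 2276 lower, and 1329 and 941 of these changed at least 2-fold. The groups did not overlap for 48.2% of genes, where chance gives 10% on average. The total stayed between 3557 and 6245 with any 1 array left out, within 1.5 times. SLC7A11 lost its call without LTED replicate 1 or 2 (adjusted p up to 0.0509), CCND1 without any LTED array, MCF7_plus_E2 replicate 2 or MCF7_minus_E2 replicate 1 or 2 (0.0965), and GLS without any LTED array or replicate 1 or 2 of either MCF7 group (0.114).

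Relative to MCF7_plus_E2, oestrogen-induced, ATF4 response and unfolded protein response genes were lower in LTED as lists, while camera did not call the ribosome biogenesis and oxidative phosphorylation lists (adjusted p 0.0887 and 0.869). Of 29 oestrogen-induced genes 18 fell and 0 rose (19 and 1 when adjusted over the list alone), CCN5 at −3.71 (SE 0.22) among them, with camera adjusted p = 1.31e-07, and adjusted p = 0.16 with an estimated correlation. Of 12 repressed genes 8 rose and 0 fell (8 rose when adjusted over the list alone), with IL1R1 at least 16.8-fold higher (2.80-fold with normexp) and BCAS1 at 2.51 (SE 0.29), and camera gave adjusted p = 0.00196, and adjusted p = 0.924 with an estimated correlation. Of 26 ATF4 response genes 8 fell and 0 rose (8 fell when adjusted over the list alone), with CHAC1 at −4.25 (SE 0.86), SLC7A5 at −2.62 and its partner SLC3A2 at −2.38 (SE 0.42), and camera gave adjusted p = 0.000153, and adjusted p = 0.924 with an estimated correlation. The arrays overlapped for that list, since LTED replicate 3 had a mean of 0.42 (−0.89 and −0.90 in the other LTED arrays), above the −0.01 of MCF7_plus_E2 replicate 3. Of 17 unfolded protein response genes 11 fell and 0 rose (12 fell when adjusted over the list alone), with the chaperone genes DNAJB9 at −2.10 (SE 0.34) and PDIA4 at −2.01 (SE 0.20). There camera gave adjusted p = 8.49e-05, and adjusted p = 0.75 with an estimated correlation. Of 25 amino acid transporters 11 fell and 2 rose (11 and 2 when adjusted over the list alone), with camera adjusted p = 0.0227, and adjusted p = 0.814 with an estimated correlation. SLC7A5, SLC3A2 and SLC7A11 are in both this list and the ATF4 response list, so these results partly count the same genes. Of 28 mitotic genes 7 fell and 0 rose (6 fell when adjusted over the list alone), CCNB1 at −1.12 (SE 0.19) among them, with camera adjusted p = 0.00667, and adjusted p = 0.995 with an estimated correlation. That camera call was lost without MCF7_plus_E2 replicate 3 (0.306), where 6 mitotic genes fell and 3 rose, 2 oestrogen-induced genes rose and 1 repressed gene fell. Without LTED replicate 3, 1 oestrogen-induced gene rose, and without MCF7_minus_E2 replicate 3, 1 unfolded protein response gene rose. Of 31 amino acid enzymes 9 rose and 6 fell (10 and 7 when adjusted over the list alone), with OAT at 2.21 (SE 0.24), GOT1 at −1.34 (SE 0.20) and camera adjusted p = 0.901, and 3 fell without LTED replicate 2 or replicate 1 or 2 of either MCF7 group. The number of ATF4 response genes that fell was 19 without MCF7_plus_E2 replicate 3, 17 without LTED replicate 3, 4 without LTED replicate 1 or 2, and 5 without MCF7_plus_E2 replicate 2.

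Both comparisons with MCF7_minus_E2 called 186 genes in common. Of these, 131 changed in opposite directions, 89 lower with oestradiol and higher in LTED and 42 the other way, and 55 changed in the same direction, 13 higher and 42 lower. Independent calls would give 34.9, 16.9, 20.1 and 29.4 in the same order. ACKR3 (−2.88 and 3.19), ESR1 (−1.19 and 1.56) and CCN5 (2.01 and −1.70) were called in opposite directions, and PSCA was lower in both (−3.26 and −2.28). Both comparisons share the MCF7_minus_E2 arrays, which in simulated data without effects gave a correlation of 0.498 between the log2 fold changes across genes and 0 shared calls. The observed correlation was −0.06, and the covariance of −0.03 was lower than the simulated one by a difference of −0.06. The simulated arrays varied independently, and the correlation between same-numbered MCF7 arrays, left out there, would lower the simulated values. Data without effects give almost no calls, so the 0 simulated shared calls are no measure for the 186. The 3 MCF7_minus_E2 arrays are too few to be split between the comparisons. With MCF7_plus_E2 replicate 3 left out the shared calls numbered 1646, of which only 748 ran in opposite directions, and on replicates 1 and 2 of each group only they numbered 3030 with 1484 opposite, so most then ran in the same direction. Without MCF7_plus_E2 replicates 1 or 2 they numbered 18 or 22 (10 or 13 opposite), without MCF7_minus_E2 replicates 1 or 2 11 or 12 (8 opposite in each case), and without LTED replicates 1 or 2 34 or 45 (23 or 31 opposite).

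Further lists moved in both directions or had few calls. Autophagy and lysosome genes had 0 of 42 called between the MCF7 groups (7 at an unadjusted p under 0.05, 0 when adjusted over the list alone), with CTSD at 1.06 (SE 0.29) and MAP1LC3B at 1.02 (SE 0.28) there, while 7 rose and 1 fell without MCF7_plus_E2 replicate 3, and 1 rose with the replicate block or without MCF7_minus_E2 replicate 3. Against MCF7_plus_E2, 13 rose and 10 fell in LTED (13 and 10 when adjusted over the list alone), with CTSD at −2.92 (SE 0.29) and NBR1 at 1.19 (SE 0.23). The number that fell there was 5 without replicate 1 or 2 of LTED or MCF7_plus_E2, 6 without MCF7_minus_E2 replicate 1 or 2, and 13 without MCF7_plus_E2 replicate 3. For mitosis 0 of 28 were called by limma between the MCF7 groups (0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone), with KIF11 at −0.61 (SE 0.37), and 9 fell without MCF7_plus_E2 replicate 3, where camera's adjusted p was 0.00214 (0.035 without MCF7_minus_E2 replicate 1). For G1/S and DNA replication, CCNE1 rose by 1.11 (SE 0.37) and GINS3 fell by 0.83 (SE 0.27) in LTED against MCF7_plus_E2, 28 of 30 were not called and 0 were called when adjusted over the list alone. Without MCF7_plus_E2 replicate 3, 14 of these rose with camera at 0.00322, CCNE1 lost its call without any other array (adjusted p up to 0.133), and GINS3 lost it without any LTED array or MCF7_minus_E2 replicate 1 or 2 (0.0892). Of receptor and co-regulator genes in the same comparison 6 rose and 4 fell (6 and 4 when adjusted over the list alone), with TFAP2C at −1.93 (SE 0.24). Receptor tyrosine kinases had 7 higher and 4 lower (7 and 5 when adjusted over the list alone), with GRB10 at −2.29 (SE 0.35), a median of −0.08 and a mean of 0.39. ERK pathway targets had 5 higher and 6 lower (5 and 6 when adjusted over the list alone), with DUSP5 at 2.15 (SE 0.30), and 3 fell without any LTED array or MCF7_plus_E2 replicate 1 or 2. Between the MCF7 groups 0 of 15 ERK targets were called (3 at an unadjusted p under 0.05, 1 fell when adjusted over the list alone), with 1 lower with the block and 2 without MCF7_plus_E2 replicate 3.

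Metabolic lists also held few calls between the MCF7 groups. The aldolase gene ALDOC rose by 1.13 (SE 0.24) among 22 glycolysis genes, and the acyl-CoA synthetase gene ACSL1 by 0.91 (SE 0.20) among 17 genes of fatty acid synthesis, with 0 lower in either list and the same counts adjusted over the list alone. Both lost their calls without any LTED array or replicate 1 or 2 of either MCF7 group (adjusted p up to 0.187 and 0.208), and ACSL1 also with the replicate block (0.0742). Of 26 TCA cycle, 23 cholesterol biosynthesis and 17 fatty acid oxidation genes, 0 were called by limma (5, 4 and 2 at an unadjusted p under 0.05; 0, 0 and 1 when adjusted over the list alone). In LTED against MCF7_minus_E2, 3 glycolysis genes rose and 1 fell (3 and 1 when adjusted over the list alone), with the lactate transporter gene SLC16A3 at 1.84 (SE 0.30), and 2 TCA cycle genes rose and 2 fell (2 and 2 when adjusted over the list alone), with DLD at −0.97 (SE 0.16). Of oxidative phosphorylation genes 6 rose and 1 fell (5 and 1 when adjusted over the list alone), with UQCRB at 1.09 (SE 0.16). Of fatty acid synthesis genes 0 rose and 3 fell (3 when adjusted over the list alone), with ELOVL5 at −1.07 (SE 0.22), and of fatty acid oxidation genes 4 rose and 1 fell (4 and 1 when adjusted over the list alone), with the carnitine palmitoyltransferase gene CPT1A at 0.83 (SE 0.16). Relative to MCF7_plus_E2 the counts were 3 higher and 4 lower for glycolysis, 4 and 7 for the TCA cycle, 3 and 4 for oxidative phosphorylation, 2 and 7 for cholesterol biosynthesis, 1 and 4 for fatty acid synthesis and 4 and 0 for fatty acid oxidation. When adjusted over the list alone these were the same but for oxidative phosphorylation, with 2 and 3. IDH1 stood at −1.51 (SE 0.23) and STARD4 at −1.96 (SE 0.36) there. Leaving out 1 array moved the higher and lower counts of LTED against MCF7_minus_E2 to 2 to 5 and 1 to 4 for glycolysis, 1 to 4 and 1 to 4 for the TCA cycle, 3 to 9 and 0 to 1 for oxidative phosphorylation, 0 to 1 and 2 to 4 for fatty acid synthesis, and 1 to 4 and 0 to 1 for fatty acid oxidation. Most of the highest counts came without MCF7_plus_E2 replicate 3. Against MCF7_plus_E2 they moved to 3 to 6 and 1 to 5, 1 to 6 and 6 to 7, 2 to 5 and 2 to 4, 0 to 6 and 4 to 6, and 4 to 6 and 0 to 1 in the same order, and to 1 to 4 and 4 to 7 for cholesterol biosynthesis. Between the MCF7 groups, the higher and lower counts without MCF7_plus_E2 replicate 3 were 2 and 8 for glycolysis, 4 and 2 for the TCA cycle, 2 and 5 for cholesterol biosynthesis, 3 and 5 for fatty acid synthesis and 1 and 2 for fatty acid oxidation. With MCF7_minus_E2 replicate 3 left out, 1 cholesterol biosynthesis gene rose and 1 fatty acid oxidation gene fell, and with the block 1 TCA cycle gene rose.

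Markers of other cell types were few among the kept genes. Of 11 measured basal markers, CAV1 (−1.29, SE 0.28) and ITGB4 (−0.89, SE 0.14) fell with oestradiol and 0 rose (3 and 1 when adjusted over the list alone), and both lost their calls without replicate 1 or 2 of any group (adjusted p up to 0.179 and 0.132), CAV1 also without MCF7_minus_E2 replicate 3 and with the block (0.0785). LTED against MCF7_minus_E2 had 4 lower and 0 higher (4 when adjusted over the list alone), with the keratin gene KRT14 at least 8.99-fold lower (2.25-fold with normexp) and CAV2 at −1.81 (SE 0.24), and against MCF7_plus_E2 4 lower and 2 higher (4 and 2 when adjusted over the list alone). Of 20 luminal markers 0 were called between the MCF7 groups (5 at an unadjusted p under 0.05, 1 lower when adjusted over the list alone). In LTED 1 rose and 3 fell against MCF7_minus_E2, with AGR2 at 1.13 (SE 0.22) and CLDN7 at −0.98 (SE 0.14), and 4 rose and 2 fell against MCF7_plus_E2, with the same counts adjusted over the list alone. KRT8 had probes called in opposite directions in both comparisons. Of 6 fibroblast markers 0 were called between the MCF7 groups (2 at an unadjusted p under 0.05, 0 when adjusted over the list alone), and in LTED COL1A1 rose (1.67, SE 0.20) and VIM (−1.80, SE 0.30) and COL5A1 (−1.21, SE 0.35) fell against MCF7_minus_E2. The counts were the same against MCF7_plus_E2, and the same adjusted over the list alone. COL5A1 lost its call without any LTED array or MCF7_minus_E2 replicate 1 or 2 (adjusted p up to 0.113), and against MCF7_plus_E2 without any array but MCF7_plus_E2 replicate 3 (0.155). Leaving out 1 array moved basal counts to 0 to 5 lower between the MCF7 groups and to 1 to 2 higher in LTED against MCF7_plus_E2, luminal counts to 2 to 5 lower against MCF7_minus_E2 and to 2 to 5 higher and 1 to 3 lower against MCF7_plus_E2, and fibroblast counts to 1 to 2 higher and 1 to 2 lower in the comparisons of LTED. Between the MCF7 groups, 3 luminal markers rose and 2 fell, 1 basal marker rose, and 1 fibroblast and 1 endothelial marker fell without MCF7_plus_E2 replicate 3, and 2 luminal markers fell without MCF7_minus_E2 replicate 3. With LTED replicate 3 left out, 1 basal marker rose and 1 blood cell marker fell in LTED against MCF7_minus_E2, and 1 blood cell marker rose between the MCF7 groups. Of 7 blood cell markers 0 were called by limma in both comparisons with MCF7_minus_E2 (1 and 0 at an unadjusted p under 0.05, 0 when adjusted over the list alone). Between LTED and MCF7_plus_E2, LCP1 rose (0.52, SE 0.14) and CD68 fell (−1.60, SE 0.51), also adjusted over the list alone. CD68 was above background on 1 of 3 LTED arrays, and it had −1.09 with lower signals set to the array's floor. With normexp it had −0.42 and was not called (limma adjusted p = 0.053). LCP1 and CD68 lost their calls without LTED replicate 1 or MCF7_plus_E2 replicate 2, LCP1 also without LTED replicate 3, and CD68 without any array but LTED replicate 3 (adjusted p up to 0.0617 and 0.125). Of 4 endothelial markers VWF rose in LTED, by 2.63 (SE 0.19) against MCF7_minus_E2 and 3.21 (SE 0.19) against MCF7_plus_E2, with 2 of 3 arrays of each MCF7 group above background. With normexp these differences were 1.295 and 1.416. No other endothelial marker was called, also adjusted over the list alone, and between the MCF7 groups 0 were called (1 at an unadjusted p under 0.05).

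Stress, survival and drug metabolism lists held few calls between the MCF7 groups. NDRG1 fell by 1.62 (SE 0.32) among 16 hypoxia genes (1 when adjusted over the list alone), PMAIP1 rose by 0.72 (SE 0.13) and BMF fell among 16 genes of the BCL2 family (2 and 2 when adjusted over the list alone), and GSTM3 fell by 1.08 (SE 0.18) among 15 genes of drug efflux and xenobiotic metabolism (3 when adjusted over the list alone). NDRG1, PMAIP1 and GSTM3 lost their calls without replicate 1 or 2 of any group (adjusted p up to 0.166, 0.158 and 0.143), NDRG1 also without LTED replicate 3, and BMF without replicate 1 or 2 of either MCF7 group (0.111). Heat shock and reference genes had 0 of 13 and 0 of 15 called by limma (2 and 2 at an unadjusted p under 0.05, 0 when adjusted over the list alone). The higher and lower counts without MCF7_plus_E2 replicate 3 were 0 and 3 for heat shock, 1 and 4 for reference genes, 3 and 2 for hypoxia, 4 and 2 for the BCL2 family and 1 and 5 for drug metabolism. With MCF7_minus_E2 replicate 3 left out, 1 heat shock gene rose and 2 BCL2 family and 2 drug metabolism genes fell, and 2 drug metabolism genes fell without LTED replicate 3. In LTED against MCF7_minus_E2, 5 hypoxia genes rose and 2 fell (6 and 4 when adjusted over the list alone), with ADM, adrenomedullin, at 2.91 (SE 0.24) and EGLN3 at 2.19 (SE 0.27). Of unfolded protein response genes 4 fell and 0 rose (4 when adjusted over the list alone), with PDIA4 at −1.56 (SE 0.20), and of ribosome biogenesis genes 4 rose and 0 fell (2 when adjusted over the list alone), with MYBBP1A at 0.77 (SE 0.19). Heat shock had 1 higher (2 without MCF7_minus_E2 replicate 3) and 1 lower (HSPD1 0.57, SE 0.12; HSPB1 −0.74, SE 0.13) and the BCL2 family 1 higher, BCL2L1 (0.50, SE 0.15), with 1 and 1 and with 0 when adjusted over the list alone. In the drug metabolism list 4 rose and 4 fell (4 and 4 when adjusted over the list alone), with the efflux pump gene ABCG2 at least 7.86-fold lower (2.17-fold with normexp) and CYP1A1 at 1.87 (SE 0.43), and of reference genes 2 rose and 2 fell (2 and 2 when adjusted over the list alone), with B2M at −1.79 (SE 0.37) and GUSB at −1.37 (SE 0.15). Relative to MCF7_plus_E2, LTED had 3 higher and 4 lower for hypoxia, 0 and 2 for heat shock, 0 and 8 for ribosome biogenesis, 3 and 1 for the BCL2 family, 7 and 6 for drug metabolism and 2 and 3 for reference genes. Adjusted over the list alone these were the same but for hypoxia, with 5 and 4. MYBBP1A lost its call without LTED or MCF7_minus_E2 replicate 1 or 2 (adjusted p up to 0.065), where the ribosome biogenesis genes that rose numbered 0 or 1, CYP1A1 lost it without the same arrays (0.0554), and BCL2L1 without LTED replicate 1 or 3, MCF7_plus_E2 replicate 1 or 2 or any array of MCF7_minus_E2 (0.11). Leaving out 1 array moved the higher and lower counts of LTED against MCF7_minus_E2 to 2 to 6 and 1 to 3 for hypoxia, 0 and 2 to 5 for the unfolded protein response, 0 to 5 and 0 to 2 for ribosome biogenesis, 0 to 4 and 0 to 1 for the BCL2 family, 0 to 4 and 3 to 5 for drug metabolism, and 1 to 2 and 2 to 5 for reference genes. Against MCF7_plus_E2 the ranges were 3 to 4 and 2 to 5 for hypoxia, 0 to 5 and 1 to 2 for heat shock, 0 to 2 and 4 to 8 for ribosome biogenesis, 2 to 5 and 1 to 4 for the BCL2 family, and 1 to 5 and 3 to 4 for reference genes. Among the tests in the last 4 paragraphs, the lowest camera adjusted p was 0.0643, for basal markers with oestradiol. That list was called without MCF7_minus_E2 replicate 1 or 2 (0.0216 and 0.0246) or LTED replicate 2 or 3 (0.0437 and 0.0445), and in LTED against MCF7_minus_E2 without LTED replicate 2 (0.0245). Against MCF7_plus_E2, cholesterol biosynthesis was called without MCF7_plus_E2 replicate 1 or 2 (0.0193 and 0.0324) and ribosome biogenesis without MCF7_plus_E2 replicate 1 (0.0451). In 18 of all 87 list tests, 0 of them called by camera, its direction, the median and the mean did not agree in sign, among them blood cell markers in each comparison, glycolysis in LTED against MCF7_minus_E2 (median −0.05 and test down, mean 0.01) and heat shock in LTED against MCF7_plus_E2 (down, 0.15).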

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

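The tests of MCF7_plus_E2 replicate 3 and of the interferon-stimulated genes below and the block for pairs of slide columns were chosen after the results were seen, and the splits of the arrays before. Probes without a gene symbol, which the gene tests do not use, held differences too: of 5241 kept, 42 were called between MCF7_plus_E2 and MCF7_minus_E2, 614 between LTED and MCF7_minus_E2 and 1050 between LTED and MCF7_plus_E2. These are 0.801%, 11.7% and 20.0% of them, against 1.67%, 21.4% and 33.5% of probes with a symbol.

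MCF7_plus_E2 replicate 3 stood apart from replicates 1 and 2 of its group. An MCF7_minus_E2 sample under its label is argued against by its mean for oestrogen-induced genes, 0.62, where MCF7_minus_E2 arrays had a mean of −0.03 and an SD of 0.11. A culture or RNA batch shared by the replicate 3 samples of both MCF7 groups could account for the pattern, since their deviations correlated by 0.48, but it was proposed from the same data. It cannot be told apart from the place on the slide, because these arrays were the ones in column 1 of the shared slide. LTED replicate 3 had column 1 of another slide, and its deviations correlated by −0.07 with MCF7_plus_E2 replicate 3 and by 0.13 with MCF7_minus_E2 replicate 3, which does not decide. A difference in the response to oestradiol in that sample stays open and was not tested. In the fits without replicate 3 this group rests on replicates 1 and 2, and the quality summary marked replicate 1 for evaluation.

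Interferon-stimulated genes were lower in LTED. Slide and scan day are argued against by the median on the shared slide, −2.78 against MCF7_minus_E2, with 19 of 28 genes lower. Spread between cultures of one group stays open: the gap between the lowest MCF7 and the highest LTED array was 2.44 and the range of the 6 MCF7 arrays 1.74, but the labels do not say whether these came from separate cultures, so that range may hold no such spread. A property of this single LTED derivation also stays open and was not tested, since the design holds 1 derivation.

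Other splits of the arrays gave fewer called genes. Of the 10 splits of 6 arrays in each comparison, 1, the real one, called 429, 3168 and 4897 genes, and the highest of the others called 0, 0 and 16 by limma, which are too few splits for a share under 0.05. At an unadjusted p under 0.05 the real splits had 3037, 4923 and 6193 genes and the highest others 3052, 400 and 1686. The 3052 came from MCF7_plus_E2 replicates 1 and 2 with MCF7_minus_E2 replicate 1 against the other 3 arrays, a split that also parts columns 3 and 4 of the slide from columns 1 and 2. With these pairs of columns as a block, 185 genes were called between the MCF7 groups, and with replicate number as a block 288. For the F-test, 1 of 100 drawn splits, the real one, reached 4646 genes, and the highest other, which kept the 3 LTED arrays together, gave 2026. This argues against a random grouping of these arrays, mostly for LTED apart from MCF7, and says little about the grouping within MCF7. The draws ignored the pairing by replicate number, and they cannot speak to spread between cultures.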

How the results depend on the processing

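The fits on replicates 1 and 2 only, the block on the 6 MCF7 arrays, the block for pairs of slide columns, and the list tests without each array other than LTED replicate 3 were chosen after the data were seen; all other alternatives were set beforehand. Over all alternatives, values of named genes kept direction and side of the threshold 9179 times, lost the call 748 times, gained it 252 times and reversed 2 times: on replicates 1 and 2 only, ASNS in LTED against MCF7_minus_E2 was −0.446 and MYC in LTED against MCF7_plus_E2 was −0.485. The cause was not tested. Quantile normalization, normexp, the authors' values, the mean of a gene's probes and slide blocks left the counts of called genes within 1.5 times. The fixed block for slide gives the same fit as leaving out LTED replicate 3, which is alone on its slide, so the same values enter the totals above under both. In the order total, higher and lower, MCF7_plus_E2 against MCF7_minus_E2 had 34, 10 and 24 calls with no filter on dim probes, 17, 5 and 12 on only the 6 arrays compared, and 13, 8 and 5 with a replicate block on the 6 MCF7 arrays. The last 2 fits leave the LTED arrays out of the estimate of the spread. On only the 6 arrays compared, LTED against MCF7_minus_E2 had 4195 calls, so fewer arrays alone do not account for the drop to 17. Estimated SDs per array were 0.416 and 0.385 between MCF7_plus_E2 replicate 3 and replicates 1 and 2, against 0.118 to 0.243 within LTED. The higher genes of MCF7_plus_E2 against MCF7_minus_E2 numbered 92 with every kept probe on its own, 265 with trend and robust, and 94 with the replicate block, which ended 18 calls of named genes and gave 5. With pairs of slide columns as a block it had 185, 49 and 136, with 99 shared calls, 66 opposite, which ended 22 calls of named genes and gave 1. Of the lists called there by camera, 1 unfolded protein response, 0 ATF4 response and 0 ribosome biogenesis genes rose under that block, and camera gained a call for cholesterol biosynthesis in LTED against MCF7_plus_E2 (0.0271). Named genes that the filter on all 9 arrays removes have no value there. With a log2 fold change of at least 1 the counts were 242, 64 and 178, then 1467, 779 and 688 for LTED against MCF7_minus_E2, then 2270, 1329 and 941 for LTED against MCF7_plus_E2, with 98 shared calls, 66 opposite. On replicates 1 and 2 only they were 6012, 2862 and 3150, then 5774, 3085 and 2689, then 8132, 4337 and 3795, with 9159 by the F-test and 3030 shared calls, 1484 opposite. With 1 array left out they ran from 18 to 3702, 7 to 1759 and 11 to 1943, then 2095 to 4754, 1080 to 2536 and 951 to 2218, then 3557 to 6245, 1903 to 3314 and 1654 to 2931. The F-test ran from 3026 to 7260, shared calls from 11 to 1646, opposite ones from 8 to 748, and camera calls from 17 to 21. Camera called 20 list tests and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. Signal over background limits the dimmest genes, whose folds are given as bounds. With normexp all 37 called bounds of named genes had smaller folds and 4 lost the call, as did 1 of 16 called values above background on some arrays of a group, all of them smaller.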

Other observations

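The tests of clustering along chromosomes were set before their results were seen, and the genes next to ESR1 were looked at after. A part of the genes that differed between LTED and MCF7_minus_E2 lay in runs of neighbours. The runs named here are consecutive windows picked because their medians in this comparison lay beyond 95% of shuffled maxima. Their medians and counts against MCF7_minus_E2 therefore describe the runs and test nothing further. Over 100 neighbouring measured genes from SULF1 to EIF3E the median log2 fold change was 0.90, with 93 higher, and over 80 from CEP41 to ZNF783 it was −0.77, with 67 lower. From VGF to PRRT4, 80 genes had a median of −0.68, with 66 lower, and from TJP1 to KNSTRN, 40 genes had −0.62, with 38 lower. Of the 10 measured genes nearest to ESR1 (1.56) in order, 5 on each side, 6 were called higher in LTED: AKAP12 (4.18, adjusted p = 5.38e-05), RMND1 (1.53, adjusted p = 0.00105), DCPH1 (1.29, adjusted p = 0.000242), ZBTB2 (0.77, adjusted p = 0.0129), MTRF1L (0.57, adjusted p = 0.0354) and SYNE1 (0.56, adjusted p = 0.0473). CNKSR3 was lower (−1.14, adjusted p = 0.0113), and CCDC170 (0.51), which with SYNE1 is next to ESR1, FBXO5 (−0.21) and RGS17 (0.77) were not called. Among all 13414 genes, 1720 were called higher. ESR1 and these neighbours lay in none of the windows beyond 95% of shuffled maxima that are counted below.

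Changes in LTED clustered along chromosomes in windows of 20 neighbouring genes. Chance placement is argued against by a permutation test over genes, in which 0 of 1000 shuffled gene orders reached the observed spread of window medians (p = 0.001, the smallest that 1000 shuffles give). Families of neighbouring related genes are argued against by a ratio of observed to shuffled spread of 2.08 with 1 gene per family. For neighbours that respond together in any comparison, the ratio was 1.20 between the MCF7 groups. It was 2.10 in LTED against MCF7_minus_E2 and 1.82 against MCF7_plus_E2. These ratios do not decide, because 3.20% of genes were called between the MCF7 groups and 23.6% in LTED against MCF7_minus_E2, and fewer changes can lower the ratio. The ratio of 1.20 was itself beyond the range of 0.948 to 1.05 that held 95% of shuffled ratios, and 0 of 1000 shuffles reached it, so neighbours moved together there too. Of 659 windows, 33 lay beyond 95% of shuffled maxima, 11 higher and 22 lower. As a hypothesis, a difference in copy number between LTED and MCF7 could account for the runs, and no DNA was measured to test it.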
